A study of Homo sapiens with 6 samples.

How the data were processed

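RNA sequencing of total RNA from 786-O cells gave 6 libraries made with a TruSeq RNA kit, 3 from control cells and 3 from cells overexpressing OGT. The authors deposited TPM per gene, in 1 column per sample, for 62703 genes with human Ensembl identifiers. The aligner, counting tool and annotation are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, although the identifiers are human. The unit was checked on the values: each column has nearly the same total, and the smallest values above 0 are higher for short than for long transcripts. No read totals were used here, so depth and counting precision are unknown. Group and replicate were taken from the sample titles, and the titles state no pairing. Same-numbered replicates were not treated as pairs: correlations of their deviations were -0.0194, 0.00264 and 0.0166, and 1 of 6 samples correlated best with its own number.

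Genes with at least 1 TPM in at least 3 samples were tested, 12645 in all, on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model, eBayes with trend and robust, two-sided). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and 1 contrast was made, OGT overexpression minus control. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists of 876 gene entries in all, with camera at an estimated correlation and fry beside it. Coordinates, GC content and transcript length came from GENCODE release 29 by Ensembl identifier, using each gene's longest transcript, protein-coding where there is one. Of the tested genes 97.7% (12348) had such a reference transcript. It need not be the transcript that the cells express, so values of single genes corrected for GC and length depend on this choice.

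Named genes followed a rule fixed before the data were examined. It took 10 genes whatever their values (OGT, OGA, EPAS1, HIF1A, ARNT, VHL, GPX4, SLC7A11, ACSL4 and TFRC). It took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 TPM in a group, replicates that separate the groups and a symbol that is no bare identifier or clone name. It also took up to 4 members of each list with the smallest adjusted p past the threshold, and markers given as checks. MGC4859 (7.97, 22.41 and 76.5 TPM in the control libraries and listed at 0 in the 3 OGT libraries) was left out because MGC was read as a clone name, a reading made after its values were seen. A further 36 genes were chosen after their values were seen: the few members in a list's minority direction, and VEGFA, CCND1 and SLC2A1. Pseudogenes and antisense transcripts are reported as uncertain, since the library's strand is not stated.

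Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, quantile normalization, each replicate left out, the replicate number as a block, the OGT gene left out, and the other set tests. Fits planned for count data were not run, since the values are TPM. Chosen after the data were seen were median centring, a filter of a mean of at least 5 TPM, and removal of each library's trend on GC content and transcript length (natural splines with 4 degrees of freedom), also with mean level as a further term. Removing the trend also centres the libraries, which partly fixes the split into higher and lower genes. Random lists, 10000 per fixed list, drawn from the 50 genes nearest to each member in GC, length and level, were chosen after the data were seen as well. The test was tried on simulated data with 12645 genes: 32.8% of log2 0.5, 83.6% of 2-fold and 97.0% of 4-fold changes were recovered with 5 false calls. With a simulated GC trend, false calls numbered 2023 without and 9 with the correction, which recovered 41.8%, 73.1% and 98.5%, against 56.7%, 82.1% and 98.5% without it. That trend was a straight line on the same GC values that the correction fits, so its removal was largely built in. No length trend was simulated, and noise was independent between genes. Changes were planted about as often up as down, and not in low genes. These rates therefore do not show how well the correction works on the real data.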

Results

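Messenger RNA levels were measured by RNA sequencing in 786-O cells, a human clear cell renal cell carcinoma line that lacks functional VHL protein and is known for constitutive HIF-2α. The 6 samples formed 2 groups of 3, control cells and cells overexpressing OGT, the enzyme that attaches O-linked N-acetylglucosamine (O-GlcNAc) to nuclear and cytosolic proteins. The series title places OGT beside HIF-2α and ferroptosis, an iron-dependent death by lipid peroxidation, so the comparison asked how OGT overexpression altered the transcriptome and those gene groups. Values were deposited as TPM, a transcript abundance scaled by length and library, and each library summed to between 993935.5 and 996951.6 TPM. TPM keeps no read total, so the sequencing depth is unknown and no counting interval is given. Between 18266 and 19499 genes were listed above 0 in a library. Genes at 1 TPM or more separated the groups, with 11885 to 12202 in control and 12743 to 12813 in OGT libraries. Across genes, which are not independent replicates, Pearson correlations of log2(TPM + 1) ran from 0.966 to 0.981 within groups and from 0.940 to 0.954 between groups, and no libraries were duplicates. The first principal component held 55.2% of the variance and separated the groups. Values below are mean ± SD over n = 3 libraries, and changes are OGT overexpression minus control on the log2(TPM + 1) scale, which understates changes of low genes.

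OGT transcript (ENSG00000147162, chromosome X, 71533083 to 71575897, plus strand, GENCODE release 29 annotation of GRCh38) was 23.1 ± 0.525 TPM in control cells and 326 ± 47.3 TPM in the overexpressing cells, a log2 change of 3.75 (SE 0.106, limma adjusted p = 1.7e-05). It lay between 270.87 and 352.92 TPM in the overexpressing libraries and between 22.57 and 23.62 TPM in the controls. OGA, which encodes the enzyme that removes O-GlcNAc, rose from 5.23 ± 0.62 to 16.2 ± 0.289 TPM (log2 change 1.47, adjusted p = 1.85e-04). EPAS1, which encodes HIF-2α (ENSG00000116016, chromosome 2, 46293667 to 46386703, plus strand), rose from 24.1 ± 0.595 to 63.5 ± 0.883 TPM (log2 change 1.36, SE 0.0598, adjusted p = 3.45e-05). Among genes with known roles in ferroptosis, the cystine transporter subunit gene SLC7A11 rose from 2.39 ± 0.219 to 8.11 ± 0.494 TPM. The transferrin receptor gene TFRC rose from 23.8 ± 2.47 to 65.5 ± 2.82 TPM. GPX4, whose product reduces lipid hydroperoxides, fell from 1434 ± 20.1 to 903 ± 28.5 TPM (log2 change -0.67, adjusted p = 4.53e-05). The deposited OGT value does not separate the endogenous from the introduced transcript.

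**Figure D1:**
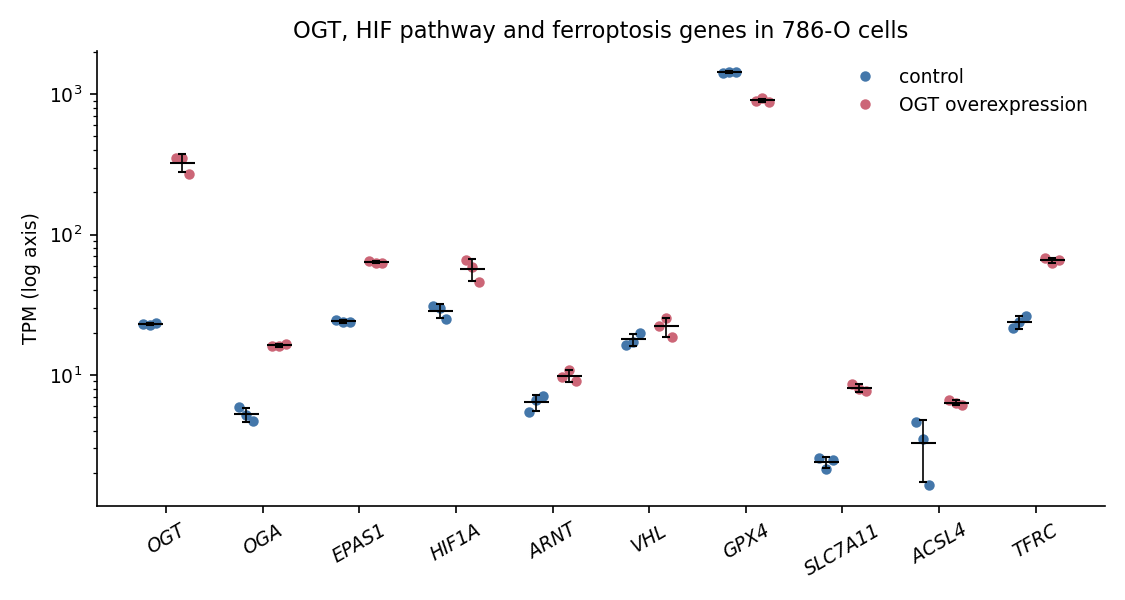
TPM on a log axis of 10 genes fixed before the data were examined, in 3 control libraries (blue) and 3 OGT overexpression libraries (red); points are libraries, bars the mean ± SD. OGT lies at 270.87 TPM or more in the overexpressing libraries and at 23.62 TPM or less in the controls, and the VHL libraries of the groups overlap.

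Of 12645 genes tested with limma, 6168 changed at a Benjamini-Hochberg adjusted p below 0.05, 4941 higher and 1227 lower with OGT overexpression, and 1502 of them changed at least 2-fold, 1351 higher and 151 lower. The median log2 change of all tested genes was 0.30, and gene changes are to be read against that shift. The split depended on scaling: 2558 genes were higher and 2245 lower after quantile normalization, and 1937 higher and 3066 lower after each library was centred on its median. The median log2 change of all tested genes was 0.019 after quantile normalization and -0.0855 after median centring. Median centring thus moved genes as a whole below 0, so part of the lower calls and sign changes under it is built in. The changes followed GC content and transcript length, with Spearman correlations across genes of -0.47 and 0.39. Genes of at most 45% GC had a median log2 change of 0.70 and genes above 60% GC one of -0.00038. The largest correlation with GC between 2 libraries of a group was 0.087 and the smallest between groups 0.368. For length the gap was narrower, at most 0.182 within a group and at least 0.288 between groups. With each library's trend on GC and length removed, a correction chosen after the data were seen, 3556 of 12348 genes changed, 1974 higher and 1582 lower, and 400 at least 2-fold, 143 higher and 257 lower. Of 6098 genes that changed as deposited and had a reference transcript, 2776 changed the same way after that correction and 33 the opposite way. Counts and tests after the correction are therefore given beside each gene list. The corrected log2 change was 2.99 for OGT, 0.99 for EPAS1, 0.76 for OGA, 0.71 for SLC7A11, 0.66 for TFRC and -0.38 for GPX4, all still past the threshold. Nothing states that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

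**Figure D2:**
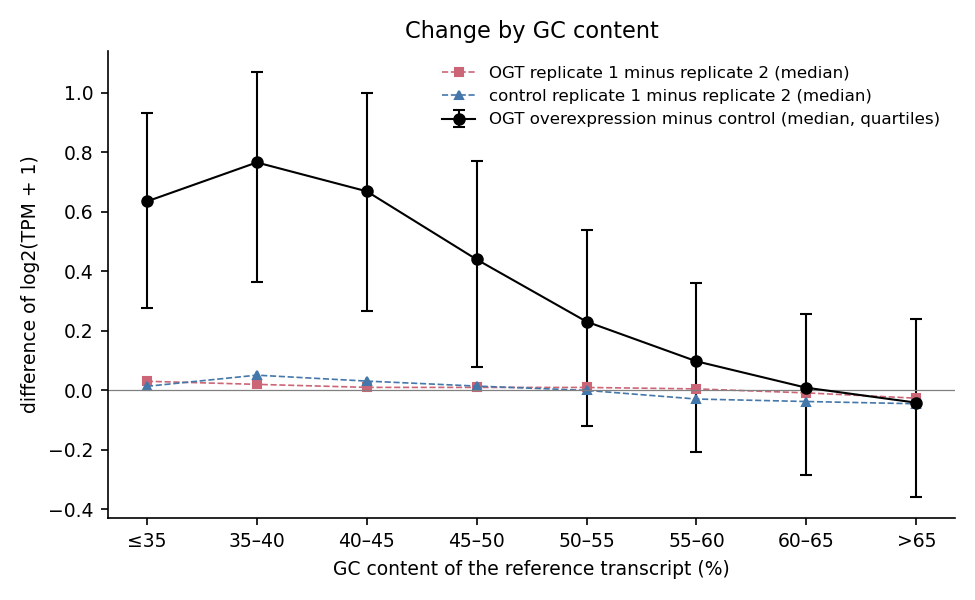
Difference of log2(TPM + 1) against the GC content of each gene's reference transcript, in percent; black points are the median OGT overexpression minus control with quartiles as bars, and coloured dashed lines are medians between replicates 1 and 2 of a group. The between-group median is 0.77 for genes of 35 to 40% GC and -0.04 for genes above 65% GC, while the within-group medians lie between -0.045 and 0.0511.

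Gene groups came from 35 lists fixed before the data were examined, tested with limma camera, which compares a list with all other genes, so its direction can differ in sign from the list's median. Member counts cover only the members that passed the filter. Camera with its preset correlation called 14 lists. With an estimated correlation camera called 0, with 3 at an unadjusted p below 0.05, and fry, which does not compare a list with other genes, called 31. After the GC and length correction camera called 11 lists, and the lowest adjusted p = 0.198 with an estimated correlation. Members named outside the fixed rule, 36 genes in all, were chosen after their values were seen. The fixed list of HIF-2α targets stood higher than other genes: 20 of 26 tested members rose and 0 fell, also 0 at an unadjusted limma p below 0.05 and 22 rose when adjusted over the list alone. A further 7 of the 33 fixed targets, among them EPO, CXCR4 and NDUFA4L2, were not tested and reached at most 3.91 TPM in any library. The list had a camera adjusted p = 0.00169. It had an adjusted p = 0.434 with an estimated correlation. PLOD2, which encodes a collagen lysyl hydroxylase, rose from 7.04 ± 0.331 to 24.3 ± 1.11 TPM (log2 change 1.65). EGFR rose from 9.64 ± 0.0173 to 28.7 ± 2.93 TPM (1.48). The vasoactive peptide gene ADM rose from 84.1 ± 4.09 to 196 ± 11.8 TPM (1.21). The lipid droplet gene PLIN2 rose from 518 ± 3 to 709 ± 6.04 TPM (0.45). Corrected log2 changes of these 4 genes were 0.96, 0.91, 1.26 and 0.21, each past the threshold, and 14 members rose and 0 fell after the correction. Camera gave an adjusted p = 2.18e-04, and adjusted p = 0.274 with an estimated correlation. Members fell under other scalings, with 9 higher and 2 lower after median centring (adjusted p = 0.00466) and 17 higher and 1 lower after quantile normalization (adjusted p = 3.94e-05). Members chosen after their values were seen were the cyclin D1 gene CCND1, which rose from 75.8 to 154 TPM (log2 change 1.01, corrected 0.59), and VEGFA, which rose from 164 to 233 TPM (log2 change 0.51) with its call lost after the correction (corrected 0.16, adjusted p = 0.0634). After median centring PLIN2 and VEGFA were no longer called (adjusted p = 0.252 and 0.205). The glucose transporter gene SLC2A1, chosen likewise, was 309 ± 66.5 and 396 ± 22.2 TPM and not called (adjusted p = 0.0726). Its log2 change of 0.38 was -0.01 after median centring, and it was called without control replicate 3 (adjusted p = 0.00801) and with a replicate block (adjusted p = 0.0279).

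Of 15 hypoxia pathway components, 7 rose and 3 fell, with no call for the list (8 higher and 3 lower adjusted over the list alone; 2 higher and 3 lower after the correction, adjusted p = 0.967). Median centring gave 3 higher and 4 lower (as deposited, camera adjusted p = 0.696). Besides EPAS1, RBX1, which encodes a ring protein of the VHL ubiquitin ligase, rose from 29.2 to 45.4 TPM (log2 change 0.62, corrected 0.51). EGLN2, which encodes a HIF prolyl hydroxylase, fell from 86.997 to 61.3 TPM (-0.50, corrected -0.54). The elongin B gene ELOB fell from 516 to 369 TPM (-0.48, corrected -0.22). HIF1AN, named because it completed the 3 that fell, had a log2 change of -0.28 (corrected -0.83). Its reference transcript is 13011 bases long, and the larger corrected fall depends on that transcript being the one expressed. As deposited, HIF1AN lost its call without control replicate 1 or 3, or OGT replicate 2 (limma adjusted p from 0.0698 to 0.0779). HIF1A rose from 28.6 ± 3.13 to 56.7 ± 10.2 TPM (log2 change 0.95) but was not called after the correction (0.26, adjusted p = 0.236). ARNT, which encodes the common HIF partner, rose from 6.38 ± 0.856 to 9.84 ± 0.96 TPM (0.56), with no call and a sign change after the correction (-0.03, adjusted p = 0.904) and no call without OGT replicate 2 (adjusted p = 0.0654). VHL was 17.9 ± 1.83 TPM in control and 22.2 ± 3.396 TPM in overexpressing cells and was not called (log2 change 0.29, adjusted p = 0.117). Its change was negative under quantile normalization, median centring and both trend corrections, and it was called without OGT replicate 3 (adjusted p = 0.0392). After median centring RBX1 and ARNT were no longer called (adjusted p = 0.0929 and 0.402). Under quantile normalization ARNT was no longer called (adjusted p = 0.431). With no filter HIF1AN was no longer called (adjusted p = 0.0663). Of 28 HIF-1 and glycolysis genes 14 rose and 4 fell (camera adjusted p = 0.696). Adjusted over the list alone, 15 were higher and 4 lower. The balance turned under some scalings and not under others. It was 5 higher and 7 lower after the correction (camera adjusted p = 0.967). After median centring it was 6 higher and 10 lower, and the median of the list went from 0.28 to -0.10. Quantile normalization kept it at 11 higher and 3 lower (camera adjusted p = 0.0761). With level as a further term of the correction it was 6 higher and 4 lower (camera adjusted p = 0.53). CA12, encoding a carbonic anhydrase, and the collagen prolyl hydroxylase gene P4HA2 rose (log2 changes 1.12 and 0.66, corrected 0.65 and 0.25). The glycolytic genes GAPDH and TPI1 fell from 9118 to 7317 TPM and from 3872 to 3049.99 TPM (-0.32 and -0.34, corrected -0.25 and -0.29). PKM and PGK1, named because they completed the 4 that fell, had log2 changes of -0.17 and -0.14 (corrected -0.24 and -0.86, adjusted p = 4.54e-04 and 5.81e-05). Without the correction PGK1 lost its call without control replicate 1 or 2, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0543 to 0.106). Under quantile normalization PKM was no longer called (adjusted p = 0.782). With no filter PGK1 was no longer called (adjusted p = 0.0707).

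In the fixed list of ferroptosis drivers 20 of 27 tested members rose and 2 fell, and 21 rose when adjusted over the list alone. A further 11 of the 38 fixed drivers were not tested and reached at most 6.91 TPM in any library. Among them were ALOX5, ALOX12, ALOX15, ALOX15B, NOX1, NOX4, CYBB and PTGS2. In camera the list reached adjusted p = 0.0263, and adjusted p = 0.407 with an estimated correlation. TFRC had a log2 change of 1.42. The haem oxygenase gene HMOX1 rose from 266 ± 0.947 to 448 ± 14.3 TPM (0.75, corrected 0.81). The spermidine acetyltransferase gene SAT1 rose from 67.03 ± 2.48 to 101 ± 4.301 TPM (0.58, corrected 0.32). PEBP1 fell from 228 ± 3.38 to 170.4 ± 5.98 TPM (-0.42, corrected -0.43). KEAP1, the other member that fell (-0.17, corrected -0.25), lost its call without control replicate 1 or 2 or 3, or OGT replicate 1 or 3 (adjusted p from 0.0696 to 0.135). ACSL4, which encodes an acyl-CoA synthetase for polyunsaturated fatty acids, rose from 3.25 ± 1.52 to 6.36 ± 0.26 TPM (0.86), a change of 0.10 after the correction (adjusted p = 0.814). It lost its call without control replicate 2, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0666 to 0.105) and was 0.55 without control replicate 3. After the same correction 12 drivers rose and 2 fell. For this list camera gave adjusted p = 0.0269, and adjusted p = 0.235 with an estimated correlation. Quantile normalization gave 12 higher and 3 lower drivers (adjusted p = 0.00806). The call of the drivers was lost after median centring (9 higher and 5 lower, adjusted p = 0.0558), among genes with a mean of at least 5 TPM (adjusted p = 0.0794) and without control replicate 2 (adjusted p = 0.05). After median centring SAT1 and ACSL4 were no longer called (adjusted p = 0.0578 and 0.223). Under quantile normalization ACSL4 was no longer called (adjusted p = 0.25). With no filter KEAP1 and ACSL4 were no longer called (adjusted p = 0.09 and 0.0926). With replicate blocks KEAP1 was no longer called (adjusted p = 0.065).

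The ferroptosis suppressor list was not called (camera adjusted p = 0.316), although 16 of 29 tested members rose and 3 fell, 17 and 3 when adjusted over the list alone. The 2 suppressors not tested, SLC40A1 and BEX1, were listed at 0 TPM in every library. The ferritin heavy chain gene FTH1 rose from 5321 ± 175 to 9297 ± 288 TPM (log2 change 0.81, corrected 0.76). The thioredoxin reductase gene TXNRD1 rose from 49.8 ± 4.21 to 128 ± 4.59 TPM (1.35, corrected 0.70). The ER chaperone gene HSPA5 rose from 155 ± 3.66 to 299 ± 4.95 TPM (0.94, corrected 0.36). Besides GPX4, the quinone reductase gene NQO1 and the glutathione synthetase gene GSS, named because they completed the 3 that fell, had log2 changes of -0.33 and -0.29 (corrected -0.83 and -0.45). The correction left 9 suppressors higher and 5 lower (adjusted p = 0.344), and median centring 9 higher and 10 lower. With no filter on low values the suppressors were called (adjusted p = 0.00672). In the iron handling list 15 of 21 members rose and HMOX2 fell (-0.48, corrected -0.50), without a call for the list (15 higher and 3 lower adjusted over the list alone; adjusted p = 0.0754). It was 10 higher and 3 lower after the correction, adjusted p = 0.0738, 10 higher and 6 lower after median centring, and called under quantile normalization (adjusted p = 0.00806) and with no filter (adjusted p = 0.00143). The RNA-binding iron chaperone gene PCBP2 rose from 297 to 474 TPM (0.67, corrected 0.26). Of 29 glutathione and NRF2 target genes 17 rose and 4 fell (17 higher and 4 lower adjusted over the list alone; adjusted p = 0.214). They were 12 higher and 5 lower after the correction, adjusted p = 0.0655, 12 higher and 11 lower after median centring, and called under quantile normalization (adjusted p = 0.0462) and with no filter (adjusted p = 0.00391), with UGDH, which makes UDP-glucuronate, at a log2 change of 1.66 (corrected 1.00) and the epoxide hydrolase gene EPHX1 at 0.51 (corrected 0.55). Those that fell were NQO1, KEAP1, AKR1B10 (-0.53, corrected -0.76) and TKT (-0.16, corrected -0.27). After median centring EPHX1 was no longer called (adjusted p = 0.0738). Under quantile normalization TKT was no longer called (adjusted p = 0.0651).

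Of 15 genes of O-GlcNAc cycling and the hexosamine pathway, OGT included, 10 rose and NAGK fell (10 higher and 1 lower adjusted over the list alone). By camera the adjusted p = 0.0469, and adjusted p = 0.482 with an estimated correlation. UAP1 and PGM3, which act in the last steps of UDP-GlcNAc synthesis, rose from 8.01 ± 1.14 to 23.1 ± 1.41 TPM and from 3.97 ± 0.195 to 12.3 ± 0.485 TPM (log2 changes 1.43 and 1.42, corrected 0.95 and 0.63). NAGK, which encodes the N-acetylglucosamine salvage kinase, had a log2 change of -0.39 (corrected -0.54) and lost its call without control replicate 3, or OGT replicate 3 (adjusted p from 0.0574 to 0.0657). With the correction 5 members rose and 1 fell, and the list was no longer called (adjusted p = 0.099). Nor was it without control replicate 1 or 2 or 3, or OGT replicate 1 or 2 (adjusted p from 0.0525 to 0.0718). Median centring gave 6 higher and 3 lower (adjusted p = 0.0157). Because the list holds the overexpressed gene itself, it was also tested with OGT left out, which ended the call (adjusted p = 0.104), as did a replicate block (adjusted p = 0.081) and a mean of at least 5 TPM (adjusted p = 0.0866). In the list of amino acid transport and glutamine genes 16 of 22 rose and 4 fell (16 higher and 4 lower adjusted over the list alone; adjusted p = 0.162). It was 9 higher and 3 lower after the correction, adjusted p = 0.155, 8 higher and 8 lower after median centring, and called under quantile normalization (adjusted p = 0.0143) and with no filter (adjusted p = 0.00672). The amino acid transporter gene SLC38A2 rose from 10.02 ± 1.14 to 37.3 ± 0.355 TPM (1.80, corrected 1.04). ASL, ASS1, GLUL and PYCR1 fell (log2 changes -0.59, -0.44, -0.46 and -0.21, corrected -0.57, -0.42, -0.96 and -0.12). GLUL lost its call without control replicate 2, or OGT replicate 2 (adjusted p from 0.0501 to 0.0531), and PYCR1 without control replicate 1 or 3, or OGT replicate 1 or 3 (adjusted p from 0.0516 to 0.0905) and after the correction (adjusted p = 0.157). With no filter NAGK and PYCR1 were no longer called (adjusted p = 0.0568 and 0.0743). With replicate blocks PYCR1 was no longer called (adjusted p = 0.0794).

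Interferon-stimulated genes formed a called list, with 31 of 39 members higher and 2 lower (31 higher and 2 lower adjusted over the list alone). The list had a camera adjusted p = 8.58e-05, and adjusted p = 0.279 with an estimated correlation. OAS2 rose from 11.5 ± 1.14 to 37.8 ± 1.305 TPM (log2 change 1.63, corrected 1.05). IFITM1 rose from 29.6 ± 0.834 to 81.6 ± 8.46 TPM (1.43, corrected 1.55). IFI6 rose from 225 ± 14.5 to 565 ± 54.99 TPM (1.33, corrected 1.55). OASL and ISG15 fell (log2 changes -0.28 and -0.30, OASL corrected -0.60). ISG15 was at 0.02 after the correction and lost its call without control replicate 2, or OGT replicate 1 or 2 (adjusted p from 0.054 to 0.0599). The correction left 23 members higher and 2 lower (adjusted p = 9.93e-07, and adjusted p = 0.198 with an estimated correlation). They were 24 higher and 4 lower after median centring (adjusted p = 4.28e-06). Under quantile normalization ISG15 was no longer called (adjusted p = 0.0674).

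The epithelial-mesenchymal transition and matrix list was called, with 27 of 30 members higher and 0 lower by limma, 1 lower at an unadjusted p below 0.05 (27 higher and 1 lower adjusted over the list alone). Camera gave an adjusted p = 1.36e-04, and adjusted p = 0.479 with an estimated correlation. The fibronectin gene FN1 rose from 2401 ± 49.2 to 4911 ± 226 TPM (log2 change 1.03, corrected 0.57). TGFBI rose from 607 ± 4.98 to 1108 ± 17.7 TPM (0.87, corrected 0.68), and CCN1 and CCN2, which encode secreted matricellular proteins, by log2 changes of 0.60 and 0.78 (corrected 0.37 and 0.58). With the correction 23 members were higher and 1 lower (adjusted p = 2.77e-06), and 17 higher and 2 lower after median centring (adjusted p = 6.9e-05). Growth factor signalling feedback genes, a called list of immediate early genes, phosphatases and EGFR ligands, included 20 higher and 0 lower members of 27, also 0 lower at an unadjusted limma p below 0.05 (20 higher and 0 lower adjusted over the list alone). In camera the list reached adjusted p = 0.00142, and adjusted p = 0.407 with an estimated correlation. The EGFR ligand gene EREG rose from 9.05 ± 0.431 to 36.5 ± 0.92 TPM (1.90, corrected 1.18). MYC rose from 74.9 ± 2.296 to 138 ± 6.29 TPM (0.87, corrected 0.75). The phosphatase gene DUSP1 rose from 182 ± 5.398 to 332 ± 7.29 TPM (0.87, corrected 0.83). KLF6 rose from 15.05 ± 0.805 to 35.1 ± 2.41 TPM (1.17, corrected 0.54). The corrected counts were 16 higher and 0 lower (adjusted p = 6.11e-05), and 11 higher and 2 lower after median centring (adjusted p = 0.00684).

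Cell cycle genes of G2 and M phase were called as a list, 24 of 29 higher and 1 lower (24 higher and 2 lower adjusted over the list alone). For this list camera gave adjusted p = 0.00169, and adjusted p = 0.279 with an estimated correlation. MKI67 rose from 5.01 ± 0.88 to 17.3 ± 0.293 TPM (log2 change 1.62, corrected 1.12). CCNA2 rose from 5.86 ± 0.369 to 14.5 ± 0.499 TPM (1.17, corrected 0.57). TPX2 rose from 48.5 ± 2.21 to 99.5 ± 4.39 TPM (1.02, corrected 0.49). CKS2, the member that fell (-0.30, corrected -0.51), lost its call without control replicate 2 (adjusted p = 0.0561). The corrected counts were 14 higher and 2 lower (adjusted p = 0.00269), and 15 higher and 5 lower after median centring (adjusted p = 0.00228). S phase genes were 19 higher and 0 lower of 29, also 0 lower at an unadjusted limma p below 0.05 (20 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0469, and adjusted p = 0.418 with an estimated correlation), with RRM1 at a log2 change of 1.32 and PCNA at 0.76 (corrected 0.70 and 0.48). Their call was lost after the correction (8 higher and 2 lower, adjusted p = 0.276) and without control replicate 1 or 2 or 3, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0537 to 0.0725). It was also lost after median centring (6 higher and 7 lower, adjusted p = 0.499), under quantile normalization (adjusted p = 0.0793), with OGT left out (adjusted p = 0.0502), with a replicate block (adjusted p = 0.081) and at a mean of at least 5 TPM (adjusted p = 0.0794).

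Genes of the unfolded protein response and ATF4 pathway were called, 23 of 34 higher and 3 lower (23 higher and 3 lower adjusted over the list alone). By camera the adjusted p = 0.0371, and adjusted p = 0.407 with an estimated correlation. The ER chaperone genes HSP90B1 and PDIA4 rose from 21.6 ± 0.722 to 68.99 ± 2.94 TPM and from 101 ± 8.99 to 244 ± 11.1 TPM (log2 changes 1.63 and 1.27, corrected 1.03 and 1.04). CRELD2, MANF and SHMT2, the members that fell, had log2 changes of -0.39, -0.34 and -0.11 (corrected -0.25, -0.23 and -0.23). SHMT2 lost its call without control replicate 1 or 2, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0681 to 0.114). With no filter SHMT2 was no longer called (adjusted p = 0.0827). With replicate blocks SHMT2 was no longer called (adjusted p = 0.0682). The corrected counts were 19 higher and 4 lower (adjusted p = 0.00287), and the list was not called after median centring (11 higher and 9 lower, adjusted p = 0.2), with a replicate block (adjusted p = 0.0916) or without control replicate 1 or 2 or 3, or OGT replicate 2 (adjusted p from 0.0537 to 0.07). Heat shock genes numbered 13 higher and 0 lower of 19, also 0 lower at an unadjusted limma p below 0.05 (13 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00959, and adjusted p = 0.434 with an estimated correlation; corrected 12 higher and 2 lower, adjusted p = 0.00195). Median centring ended the call of the heat shock list, with 6 higher and 4 lower (adjusted p = 0.0558). HSP90AA1 rose from 16.3 ± 1.02 to 67.6 ± 1.82 TPM (1.99, corrected 1.40). HSPD1 rose from 36.3 ± 0.994 to 98.1 ± 1.02 TPM (1.41, corrected 0.90). Of 30 autophagy and lysosome genes 23 were higher and 0 lower, also 0 lower at an unadjusted limma p below 0.05 (24 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00126, and adjusted p = 0.407 with an estimated correlation; corrected 16 higher and 2 lower, adjusted p = 3.88e-04). Autophagy and lysosome genes were 11 higher and 3 lower after median centring (adjusted p = 0.0171). LAMP2, which encodes a lysosomal membrane protein, rose from 13.8 ± 1.04 to 37.6 ± 1.14 TPM (1.39, corrected 0.67). The lysosomal protease gene CTSB rose from 355 ± 0.913 to 574 ± 10.7 TPM (0.69, corrected 0.38).

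Splicing factor genes were called as deposited, 24 of 31 higher and 2 lower (24 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00264, and adjusted p = 0.479 with an estimated correlation), but not after the correction (9 higher and 4 lower, adjusted p = 0.39). Splicing factor genes were 16 higher and 3 lower after median centring (adjusted p = 0.00211). HNRNPA2B1 rose from 59.997 ± 4.98 to 147 ± 2.96 TPM (log2 change 1.28, corrected 0.58), and HNRNPC fell from 1349 ± 12.6 to 898 ± 36.9 TPM (-0.59, corrected -1.34). LUC7L, the other member that fell (-0.54, corrected -0.61), lost its call without control replicate 1 or 2, or OGT replicate 1 or 2 (adjusted p from 0.0509 to 0.111). Nuclear oxidative phosphorylation genes were the called list with the most members lower, 22 of 44, with 10 higher (10 higher and 22 lower adjusted over the list alone). The list had a camera adjusted p = 3.37e-06, and adjusted p = 0.407 with an estimated correlation. NDUFB8 fell from 1047 ± 41.5 to 598 ± 15.2 TPM (-0.81, corrected -0.61). NDUFV1 fell from 322 ± 3.63 to 237 ± 7.14 TPM (-0.44, corrected -0.47). CYC1 fell from 802 ± 26.3 to 607 ± 16.5 TPM (-0.40, corrected -0.18). After the correction 26 were lower and 3 higher (camera adjusted p = 4.86e-06, and adjusted p = 0.274 with an estimated correlation). Median centring gave 5 higher and 32 lower (camera adjusted p = 4.28e-06). The 13 mitochondrially encoded mRNAs were not called as a list (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.792); 6 rose, such as MT-ND4 from 2871 to 3848 TPM (0.42; not called after the correction, adjusted p = 0.349), and MT-ND3 fell (-0.21, corrected -0.37, call lost without control replicate 2 or 3, or OGT replicate 2 or 3 (adjusted p from 0.0556 to 0.0785)), while their median of 0.18 became -0.21 after median centring. They were 0 higher and 1 lower after the correction, adjusted p = 0.871, 0 higher and 6 lower after median centring, and called upward under quantile normalization (8 higher and 0 lower, adjusted p = 0.0182). Ribosomal protein genes stood lower than other genes as deposited (18 higher and 18 lower adjusted over the list alone; camera adjusted p = 0.00142, and adjusted p = 0.58 with an estimated correlation), 16 of 47 higher and 18 lower, with no call after the correction (16 higher and 24 lower, adjusted p = 0.0657) and an opposite direction under quantile normalization (21 higher and 13 lower, adjusted p = 0.718). They were 5 higher and 35 lower after median centring (adjusted p = 4.3e-05). RPL15 fell from 6769 ± 176 to 3121 ± 27.7 TPM (-1.12, corrected -1.65). RPL11 rose from 459 ± 11.3 to 1028 ± 38.7 TPM (1.16, corrected 1.08). After median centring MT-ND4 was no longer called (adjusted p = 0.747). Under quantile normalization MT-ND3 was no longer called (adjusted p = 0.0786). With no filter LUC7L and MT-ND3 were no longer called (adjusted p = 0.0903 and 0.0583). With replicate blocks LUC7L and MT-ND3 were no longer called (adjusted p = 0.0697 and 0.0528). With level removed too MT-ND3 was no longer called (adjusted p = 0.0534).

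**Figure D3:**
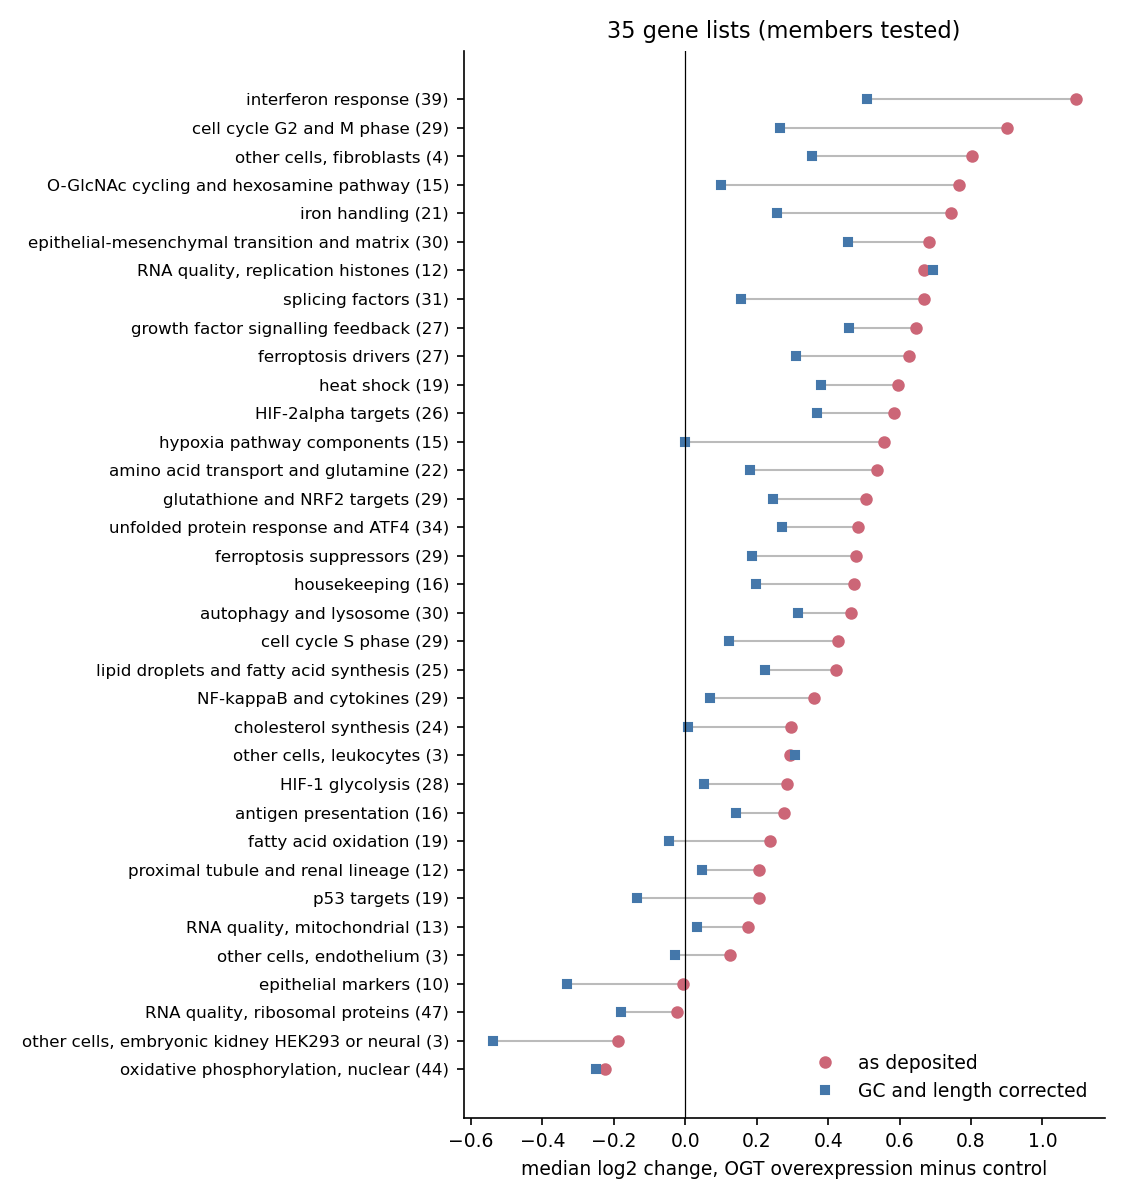
Median log2 change, OGT overexpression minus control, of the tested members of 35 gene lists fixed before the data were examined; red circles are the values as deposited, blue squares those after the GC and length correction, and the number tested is in parentheses. The interferon list has medians of 1.09 and 0.51, and the nuclear oxidative phosphorylation list medians of -0.22 and -0.25.

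Besides OGT itself, the 12 largest rises by the naming rule included the translation initiation factor gene EIF5, which rose from 4.83 ± 0.749 to 38.3 ± 4.62 TPM (log2 change 2.75, corrected 1.98). ASPH, which encodes aspartate β-hydroxylase, rose from 27.4 ± 2.15 to 114 ± 7.87 TPM (2.02, corrected 1.24). RFC1, which encodes the large clamp loader subunit, the neprilysin gene MME and the long noncoding RNA LINC00520 rose as well (log2 changes 2.11, 2.11 and 2.23, corrected 1.36, 1.33 and 1.86). TCEA1 spread from 57.42 to 227.84 TPM in the overexpressing libraries (2.54, and 1.92 without OGT replicate 2), and CLASP1 from 6.15 to 28.22 TPM (2.07), with no call after the correction (1.48, adjusted p = 0.0644). The pseudogenes BZW1P2, ITGB1P1, RNF216P1 and SRP9P1 (2.34, 2.21, 2.22 and 3.47) can share reads with their parent genes and are uncertain; SRP9P1 was listed at 0 in 2 control libraries and had log2 changes of 4.37 and 2.59 without OGT replicate 1 or 2.

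Among the 12 largest falls, the prefoldin subunit gene PFDN4 fell from 185 ± 6.805 to 20.1 ± 3.61 TPM (log2 change -3.16, corrected -3.51). The ribosome biogenesis gene RBIS fell from 178 ± 24.6 to 31.8 ± 10.2 TPM (-2.49, corrected -2.71). TMEM265, TEX22 and CLEC2B fell as well (log2 changes -2.38, -2.30 and -1.91, corrected -2.16, -2.31 and -2.33). RN7SK, a small nuclear RNA without a poly(A) tail, fell from 76.8 ± 18.3 to 4.38 ± 0.682 TPM (-3.84, corrected -3.46). Replication histone genes, whose mRNAs mostly lack a tail too, were 5 higher and 1 lower of 12 tested (camera adjusted p = 0.673). After the correction 5 were higher and 0 lower (camera adjusted p = 0.0371, and adjusted p = 0.274 with an estimated correlation). The 10 members not tested reached at most 2.14 TPM in any library. Whether the measured histone transcripts carried a tail was not determined. The list therefore does not show how RNA without a tail changed as a class. Antisense transcripts and pseudogenes are uncertain because reads may be shared and strand use is not stated: SPRY4-AS1 (-2.64; 34.7 TPM in control replicate 1 and at most 2.78 TPM elsewhere; -1.51 without that library and -3.29 without control replicate 3; call lost without control replicate 2, or OGT replicate 1 or 2 or 3 (adjusted p from 0.051 to 0.124)), TMSB15B-AS1 (-1.85) and RPL38P4 (-2.41; -3.04 without OGT replicate 2 and -1.51 without OGT replicate 3; call lost without control replicate 1 or 2 or 3, or OGT replicate 1 (adjusted p from 0.0534 to 0.0783)). Calls of the following also rested on particular libraries: ADAMTS18 (-2.43, and -1.83 without control replicate 1) lost its call without control replicate 2, or OGT replicate 2 or 3 (adjusted p from 0.0512 to 0.0698), GOLGA7B-DT (-2.19, and -2.85 without control replicate 3) without control replicate 1 or 2, or OGT replicate 3 (adjusted p from 0.0634 to 0.0654), and RALGPS1 (-2.12, and -2.85 without control replicate 2) without control replicate 1 or 3, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0582 to 0.0848). After the correction GOLGA7B-DT and SPRY4-AS1 were not called (log2 changes -1.84 and -2.51, limma adjusted p = 0.054 and 0.0755). With no filter SPRY4-AS1, RPL38P4, GOLGA7B-DT and RALGPS1 were no longer called (adjusted p = 0.106, 0.0701, 0.0537 and 0.0692). With replicate blocks SPRY4-AS1 was no longer called (adjusted p = 0.0566). At a mean of at least 5 TPM SPRY4-AS1 was no longer called (adjusted p = 0.0599).

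Markers fixed for other cell types were mostly below the filter. Leukocyte markers had 3 tested of 18, with CD68, also a lysosomal gene, up from 64.8 to 108 TPM (0.72, list adjusted p = 0.985; 1 higher and 0 lower adjusted over the list alone; 1 higher and 0 lower after the correction, adjusted p = 0.646), and the 15 markers not tested reached at most 12.23 TPM in any library. Endothelial markers had 3 tested of 14, with EGFL7 down from 89.9 to 63.6 TPM (-0.49, list adjusted p = 0.303; 0 higher and 1 lower adjusted over the list alone; 0 higher and 1 lower after the correction, adjusted p = 0.39). Fibroblast markers had 4 tested of 15, of which C1R, C1S and PDPN rose (0.96, 0.72 and 0.88, list adjusted p = 0.448; 3 higher and 0 lower adjusted over the list alone; 1 higher and 0 lower after the correction, adjusted p = 0.277); C1S and PDPN were not called after the correction (adjusted p = 0.35 and 0.176), and C1S lost its call without control replicate 2, or OGT replicate 1 or 2 (adjusted p from 0.069 to 0.0905). Embryonic kidney or neural markers had 3 tested of 13, with TUBB3 down from 201 to 163 TPM (-0.31, list adjusted p = 0.104; 0 higher and 1 lower adjusted over the list alone; 0 higher and 2 lower after the correction, adjusted p = 0.0655). Of 16 housekeeping genes 9 rose, such as YWHAZ (1.32, corrected 0.55), and 4 fell, among them RPLP0 (-0.66, corrected -0.55), PGK1 and OAZ1 (-0.13, call lost without control replicate 1 or 2 or 3, or OGT replicate 1 or 2 (adjusted p from 0.0583 to 0.143)), without a call for the list (11 higher and 4 lower adjusted over the list alone; adjusted p = 0.559). The list was 6 higher and 5 lower after the correction, adjusted p = 0.446, 7 higher and 6 lower after median centring, and called under quantile normalization (adjusted p = 0.0446); OAZ1 was not called after the correction (adjusted p = 0.728) and turned to 0.067 with level as a further term. After median centring C1S and PDPN were no longer called (adjusted p = 0.229 and 0.114). Under quantile normalization C1S, PDPN and OAZ1 were no longer called (adjusted p = 0.247, 0.123 and 0.814). With no filter C1S and OAZ1 were no longer called (adjusted p = 0.0596 and 0.0869). With replicate blocks C1S and OAZ1 were no longer called (adjusted p = 0.0637 and 0.052).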

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

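Median centring, the trend corrections and the filter of a mean of at least 5 TPM were chosen after seeing the data. The other alternatives were planned, and those for count data were not run because the values are TPM. Of 77 counts of genes or lists under the alternatives 61 lay within 1.5 times the reported count and 16 did not. Of 595 values of the 35 lists 486 kept direction and side of the threshold, 52 lost and 24 gained a call, and 33 reversed. Outside fry no reversed list had an adjusted p below 0.243. Of 2746 values of 184 named genes 2529 kept both, 200 lost and 3 gained a call, and 14 reversed. Leaving out each library in turn gave 4888 to 5718 changed genes (3899 to 4604 higher, 989 to 1127 lower, 1428 to 1612 at least 2-fold), 10 to 13 lists, and an OGT log2 change of 3.69 to 3.88. Adjusted p over the same settings ran from 0.0017 to 0.0038 for HIF-2α targets, 0.021 to 0.05 for ferroptosis drivers, with the call lost without control replicate 2, and 0.283 to 0.395 for suppressors. An estimated correlation gave adjusted p of 0.434 for HIF-2α targets and 0.407 for drivers, and 0 lists by camera (3 at an unadjusted p below 0.05). Fry gave 31 lists and an adjusted p of 1.28e-04 for suppressors. It does not compare a list with other genes, and reversed antigen presentation 6.2e-04, cholesterol synthesis 0.0843, epithelial markers 0.00353, fatty acid oxidation 5.14e-04, NF-κB 4.33e-04, leukocytes 0.00322 and p53 targets 0.0015. A pseudocount of 0.1 gave 2313 genes changed at least 2-fold, since it shrinks low genes less, and no filter gave an adjusted p of 0.00672 for suppressors. With no filter the lists reversed were fatty acid oxidation 0.572, NF-κB 0.379, fibroblasts 0.963 and p53 targets 0.561. Quantile normalization gave 2558 higher, 2245 lower and 793 changed at least 2-fold, with the lists reversed antigen presentation 0.718, NF-κB 0.748, leukocytes 0.951 and ribosomal proteins 0.718, and log2 changes of -0.000102 for HAVCR1 and -0.0185 for VHL. Median centring gave 1937 higher, 3066 lower and 857 changed at least 2-fold, an adjusted p of 0.0558 for drivers, reversed lists HIF-1 glycolysis 0.683, leukocytes 0.904, renal lineage 0.9 and mitochondrial mRNAs 0.243, and log2 changes of -0.0608 for MT-ATP6, -0.0108 for SLC2A1 and -0.101 for VHL. The median log2 change of all tested genes was then -0.0855, so part of the lower calls is built in. GC and length correction gave 3556 changed, 1974 higher and 400 at least 2-fold, reversed lists antigen presentation 0.733, HIF-1 glycolysis 0.967, NF-κB 0.871, leukocytes 0.646 and mitochondrial mRNAs 0.871, and log2 changes of -0.0278 for ARNT, 0.0211 for ISG15, -0.0443 for PMAIP1 and -0.235 for VHL. With level added these were 3526, 1912 and 376, and -0.0748 for ARNT, 0.0945 for ISG15, 0.067 for OAZ1, -0.109 for PMAIP1 and -0.284 for VHL. The lists reversed with level added were antigen presentation 0.554, NF-κB 0.879 and leukocytes 0.569. A mean of at least 5 TPM gave 907 genes changed at least 2-fold, with 8190 genes tested, an adjusted p of 0.0794 for drivers, and reversed lists hypoxia components 0.973 and leukocytes 0.973. With the replicate number as a replicate block 5473 genes changed, and leukocytes reversed (0.912). Leaving out libraries gave 0.407 to 0.969 for mitochondrial mRNAs, reversed without control replicate 1 (0.877), and 0.785 to 0.998 for leukocytes, reversed without OGT replicate 1 or 2 (0.941 and 0.875). Numbers after list names are adjusted p. Except where a reason is given, the cause was not tested. Depth is unknown, so what it limits cannot be stated.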

Other observations

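All tests of explanations in this part were chosen only after the results were seen. Antigen presentation genes moved both ways, with 8 of 16 higher and 6 lower (8 higher and 6 lower adjusted over the list alone). Camera gave an adjusted p = 0.496. They were 6 higher and 4 lower after the correction, adjusted p = 0.733, and 4 higher and 8 lower after median centring. The peptide-loading gene TAPBP rose from 139.9 ± 5.701 to 267 ± 22.3 TPM (log2 change 0.93, corrected 0.74). B2M rose from 692 ± 29.2 to 1177 ± 22.8 TPM (0.77, corrected 0.32). The immunoproteasome gene PSMB10 fell (-0.68, corrected -0.47). Of 29 NF-κB and cytokine genes 15 rose and 6 fell (16 higher and 6 lower adjusted over the list alone; adjusted p = 0.792). They were 5 higher and 4 lower after the correction, adjusted p = 0.871, and 5 higher and 11 lower after median centring, with the chemokine gene CXCL5 at 1.02 (corrected 0.45), ICAM1 at 0.59 (corrected 0.43) and the complement gene C3 at -0.64 (corrected -0.91). Among 10 epithelial markers 2 rose and 3 fell (2 higher and 4 lower adjusted over the list alone; adjusted p = 0.12; 1 higher and 4 lower after the correction, adjusted p = 0.277; 2 higher and 5 lower after median centring). With no filter the epithelial markers were called (adjusted p = 0.0331). The tight junction gene CLDN1 rose from 21.9 to 55.6 TPM (1.30, corrected 0.62), TJP1 rose (1.20) without a call after the correction (adjusted p = 0.0601), and the keratin genes KRT18 and KRT19 fell (-0.35 and -0.56, corrected -0.29 and -0.38). Renal lineage genes numbered 6 higher and 0 lower of 12, with 1 lower at an unadjusted limma p below 0.05 (6 higher and 0 lower adjusted over the list alone; adjusted p = 0.758). They were 2 higher and 0 lower after the correction, adjusted p = 0.698, and 2 higher and 3 lower after median centring. PAX8 rose from 136 to 199 TPM (0.55, corrected 0.32), and VCAM1 and HAVCR1 rose (0.79 and 0.41) without calls after the correction (adjusted p = 0.171 and 0.553). HAVCR1 also lost its call without control replicate 3, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0567 to 0.0848). After median centring PAX8 and HAVCR1 were no longer called (adjusted p = 0.163 and 0.919). Under quantile normalization HAVCR1 was no longer called (adjusted p = 1). With replicate blocks HAVCR1 was no longer called (adjusted p = 0.0668).

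Genes of lipid droplets and fatty acid synthesis were 17 higher and 3 lower of 25 (18 higher and 3 lower adjusted over the list alone). In camera the list reached adjusted p = 0.426. They were 7 higher and 2 lower after the correction (camera adjusted p = 0.277), and 5 higher and 7 lower after median centring. The desaturase gene SCD rose from 22.2 ± 0.803 to 44.9 ± 2.15 TPM (0.98, corrected 0.39). DGAT1, PLIN3 and FABP6 fell (-0.36, -0.21 and -0.64, corrected -0.48, -0.23 and -0.43). DGAT1 lost its call without control replicate 1 or 3, or OGT replicate 2 or 3 (adjusted p from 0.0536 to 0.0682), and FABP6 after the correction (adjusted p = 0.0768). Of 19 fatty acid oxidation genes 7 rose and 3 fell (8 higher and 3 lower adjusted over the list alone; adjusted p = 0.792). The excess of rises was not seen under the other scalings: 0 higher and 4 lower after the correction, adjusted p = 0.39, 0 higher and 5 lower after median centring and 3 higher and 3 lower after quantile normalization. HADHA rose (0.48) without a call after the correction (adjusted p = 0.13), and ACADVL, ECI1 and ETFB fell (-0.60, -0.84 and -0.53, corrected -0.62, -0.69 and -0.97). Cholesterol synthesis genes were 8 higher and 5 lower of 24 (9 higher and 5 lower adjusted over the list alone; adjusted p = 0.448). More fell than rose under the other scalings: 1 higher and 6 lower after the correction, adjusted p = 0.264, 3 higher and 9 lower after median centring and 3 higher and 8 lower after quantile normalization. As deposited, the list included CYP51A1, which rose (1.32, corrected 0.66), and the mevalonate pathway genes PMVK, FDPS and MVD, with EBP and ACAT2, which fell (-1.08, -0.48, -0.44, -0.61 and -0.30, corrected -0.89, -0.41, -0.33, -0.65 and -0.65). Of 19 p53 targets 7 rose and 3 fell (7 higher and 3 lower adjusted over the list alone; adjusted p = 0.783). They were 3 higher and 3 lower after the correction, adjusted p = 0.773, 2 higher and 8 lower after median centring and 3 higher and 5 lower after quantile normalization. GADD45A rose from 76.2 to 125 TPM (0.71, corrected 0.66), and PMAIP1 rose (0.43) but was at -0.04 after the correction. FDXR, TP53I3 and DDB2 fell (-0.55, -0.57 and -0.25, corrected -0.47, -0.54 and -0.28). TP53I3 lost its call after the correction (adjusted p = 0.066) and without control replicate 1 or 2 or 3, or OGT replicate 1 or 3 (adjusted p from 0.0551 to 0.0951), and DDB2 without control replicate 1 or 3, or OGT replicate 1 or 2 or 3 (adjusted p from 0.0766 to 0.11). Replication histone genes, fixed as an RNA quality list, were 5 higher and 1 lower of 12 (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.673), with H1-2 and H2BC12 up (0.85 and 0.58, corrected 1.15 and 0.98) and H2AC20 down (-1.02, not called after the correction, adjusted p = 0.111). They were 1 higher and 1 lower after median centring and 2 higher and 1 lower after quantile normalization, and called after the correction (5 higher and 0 lower, adjusted p = 0.0371, and adjusted p = 0.274 with an estimated correlation). After median centring HADHA, PMAIP1 and H2BC12 were no longer called (adjusted p = 0.284, 0.702 and 0.151). Under quantile normalization PMAIP1 was no longer called (adjusted p = 0.134). With no filter DGAT1, TP53I3 and DDB2 were no longer called (adjusted p = 0.0536, 0.0852 and 0.0833). With replicate blocks DDB2 was no longer called (adjusted p = 0.0707). Medians of the antigen presentation, NF-κB, renal lineage, fatty acid oxidation, cholesterol and p53 lists were positive as deposited and negative after median centring. The median of all tested genes was also negative after that centring (-0.0855).

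More genes were higher (4941) than lower (1227) with OGT overexpression. A smaller part of the TPM in abundant genes, 43.5% in control and 39.4% in OGT libraries for the top 100, implies a shift of all other genes by 0.102. As the whole cause this shift is argued against by the gap between GC classes, which a common shift leaves at 0. Genes above 60% GC were not raised that far (median log2 change -0.00038). As a part of the cause the shift still cannot be told apart from a trend, since both can act on the same genes and a trend could offset it there. A trend on GC content and transcript length between the libraries may account for much of the excess: the gap between genes of at most 45% and above 60% GC was 0.695, against at most 0.0747 between libraries of a group. Whether that trend came from library preparation or from the cells stays open, since each group holds its own libraries. The 10 splits of the 6 samples are too few for a share under 0.05: 1 gave as many genes, with 6168 in the real split and at most 1 in the others, 1502 and 1 at 2-fold, and 3556 and 9 after the correction.

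The HIF-2α target list stood higher than other genes with OGT overexpression. The trend on GC and length is argued against as its whole cause by an adjusted p of 2.18e-04 after its removal. Of 10000 random lists matched on GC, length and level 0.3% had as high a median. Each member's stand-in was drawn separately, so the share takes no account of members that change together. Nor was a small share particular to this list. It was 0% for interferon, 0.01% for growth factor feedback and 0.03% for matrix genes, but 52.8% for HIF-1 glycolysis. For replication histones, a list fixed as an RNA quality check, the share was 0.04%, smaller than for the HIF-2α targets. A response to OGT or to the raised EPAS1 transcript is a candidate explanation of the HIF-2α target list that was not tested. That list is not called by camera with an estimated correlation (adjusted p = 0.434). For the number of lists called, the splits are again too few for a share under 0.05, with 14 in the real split and at most 3 in the others.

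Nuclear oxidative phosphorylation genes stood lower than other genes with OGT overexpression. Removal of the trend on GC and length left an adjusted p of 4.86e-06, which argues against that trend as the whole cause. Removal with level as a further term left 1.62e-05, which argues against smaller changes of abundant genes as the whole cause. Both values are from camera at its preset correlation. Of 10000 matched random lists 0% had as low a median, a share that takes no account of members that change together. A lower output of these genes in the overexpressing cells may be involved, a hypothesis that these data do not separate from a difference in culture. Camera with an estimated correlation does not call the list (adjusted p = 0.407 as deposited and 0.274 after the GC and length correction).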
